A study of Mus musculus with 6 samples.

How the data were processed

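Messenger RNA attached to ribosomes was measured on 6 Affymetrix whole-transcript mouse gene arrays, 3 after saline and 3 after lipopolysaccharide (LPS), per the labels. The mice carried a Flag- and EGFP-tagged ribosomal protein, RPL10a, under the CD11b promoter, which is active in myeloid cells. Translating ribosome affinity purification (TRAP) pulls down the tagged ribosomes with the mRNA they hold. Each array was labelled from 100 ng of ribosome-associated RNA from a pool of 5 mice aged 2 to 3 months, per the labels' protocols and descriptions. The tissue is not given in the sources used here, so marker genes of several cell types were used as descriptions. After the data were seen they also served in the tests of neuronal and astrocyte RNA given at the end.

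The deposited value table held log2 values per transcript cluster and array. The authors made them with RMA in Affymetrix Expression Console, per the submitters' processing notes, and used Transcriptome Analysis Console, version 3.0 per the series' design text. RMA subtracts background, equalises the arrays at probe level and summarises probes, so a fold is compressed for dim clusters and neighbouring array medians can still differ after summary. The genome build and the versions of the first 2 tools are not given in the sources used here. Of the 41345 clusters in the value table, 34472 were listed in the authors' deposited comparison table, and these were tested. The other 6873 carried no annotation in the tables used here and entered only an alternative. The authors' deposited comparison table gave, per the file headers, group averages in log2 units (bi-weight means), a signed linear fold, an analysis-of-variance p-value and its adjusted p-value. Its p-values lay within 0.001 of an unmoderated equal-variance test on the value table for 99.997% of clusters.

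Gene names came from the authors' deposited comparison table. A cluster was given a gene where it had a symbol, its RefSeq accessions matched at most 1 gene of the GRCm38.p6 gene table, and its description named 1 gene or, where it named several, its accessions matched exactly the gene of the symbol. By this rule 27600 clusters had 1 gene, 2121 had several and 4751 had no symbol. Of the clusters with a symbol, 23058 matched the gene table by accession, and 1312 clusters with 1 gene carried a symbol that differs from the current one. Of the 26438 genes, 894 had more than 1 cluster, and each gene was represented by its cluster with the highest mean over the 6 arrays. The rule that a description with several names could still be used was set after seeing the data, and 995 clusters rest on it. Gene symbols are written as the deposited table gives them.

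Differences are LPS minus saline in log2 units, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with group as the only term, and Benjamini-Hochberg adjustment over the 34472 clusters at a threshold of 0.05. Errors given as SE are limma's moderated standard errors, and errors given as SD are between the 3 arrays of a group. Before the data were examined, 36 gene lists were fixed, and 795 of their 822 memberships were measured. Each list was tested with limma's camera (two-sided, preset inter-gene correlation 0.01) against all other genes, again with the correlation estimated from the residuals, and with fry, which asks whether a list moves at all. Members of a list past the threshold were counted after adjustment over all clusters and after adjustment over the list alone. The adjustment over a list alone was not corrected for the number of lists. Genes to be named were fixed before the data were examined as up to 10 risen and 10 fallen genes past the threshold without overlap between the groups, up to 4 members of each list (those past the threshold, otherwise the 2 members with the greatest absolute difference), and 24 genes chosen for their known roles. Gapdh, among the 24, had no cluster with exactly 1 gene. Other genes named in the text were chosen after their values were seen, either for passing the threshold within their list alone or for a small p.

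Samples with the same number in both groups were checked for pairing. The labels number the arrays 1 to 3 in each group and do not say what a number stands for. Deviations from the group means correlated across clusters by 0.27 for the arrays numbered 1, 0.12 for those numbered 2 and 0.56 for those numbered 3, and the first principal component parted both arrays numbered 3 from the rest. All 3 values over the clusters tested exceed 0.1, the criterion used here for a pairing. The main fit still had group as its only term, and the replicate block was run only as an alternative. Its values are given where it changes a call. Over all 41345 clusters the values were 0.21, 0.08 and 0.46, so for number 2 the criterion holds only over the clusters tested. Saline 2 correlated more with LPS 1 (0.41) than with LPS 2, so the pairing is not evident for numbers 1 and 2. Deviations sum to 0 within a group, so the shared offset of the arrays numbered 3 alone raises the values among the others. Those for numbers 1 and 2 are therefore no evidence of pairing. No 2 arrays were alike enough to be 1 sample deposited more than once, since the SD of their differences was at least 0.288.

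Alternatives were the replicate block, each array left out in turn, repeated quantile normalization, centring on the array median, on the median level of ribosomal protein genes or, chosen after seeing the data, on their mean, a filter on dim clusters, clusters with 1 gene only, an intensity trend with a robust prior, array weights, the methods' unmoderated test, the mean over a gene's clusters, an estimated correlation, and other choices of list members. The other deposited table holds group averages and no values per array, so it could not stand in for the value table. The test was tried on simulated data with the means and spreads of these arrays, 34472 clusters, 200 changed clusters and 10 draws. For LPS against saline, limma called 36.8% of clusters simulated at a log2 change of 1, 82.4% at 2, 95.6% at 3 and 98.4% at 4. With the offset of the arrays numbered 3 put into the simulation, the shares were 20.2%, 82.0%, 97.6% and 98.6%. The changed clusters were drawn at random with the same error SD in both groups, and 200 true changes ease the adjustment. These shares therefore do not hold for genes whose LPS arrays spread widely. Saa3, with a difference of 4.83 and an SD of 1.79 after LPS, did not pass (limma adjusted p = 0.300). In 20 draws over 26438 genes, a list of 20 members shifted by 0.5 was called by camera 20 times. Errors were drawn independently between genes in these draws. The list shifted was complement, whose members had an estimated correlation of 0.20 in the real arrays. The draws therefore cannot tell how often camera would call a list whose members vary together. The number of arrays, 3 per group, limits the precision.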

Results

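RNA purified through a ribosome tag driven by the CD11b promoter was profiled 24 h after an injection of saline or of 5 mg/kg LPS, the endotoxin of Gram-negative bacteria that is sensed by the receptor TLR4. Each group had 3 arrays, each from a pool of 5 mice. The comparison asks which transcripts in the purified RNA differ after LPS. Markers of other cell types also gave high signals. The median log2 signal in saline was 10.9 for neuron markers against 7.14 for resting microglia markers. Signals of different genes depend on their probes, so these levels do not measure the share of a cell type. The differences below are those of the purified RNA, and the cell type in which each arose was not measured. Median log2 signals over the 34472 clusters were 5.17, 5.15 and 5.35 in the saline arrays and 5.17, 5.19 and 5.42 in the LPS arrays. The first principal component, with 53.2% of the variance, parted both arrays numbered 3 from the other 4. The second, with 16.3%, parted the 3 saline arrays from the 3 LPS arrays. Differences below are on the deposited scale.

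**Figure D1:**
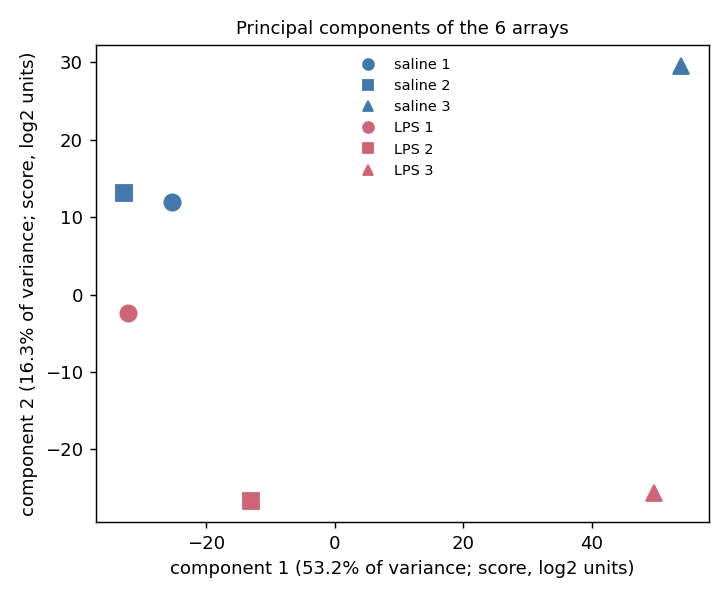
Scores of the 6 arrays on the first and second principal components of the log2 RMA values (horizontal axis, 53.2% of variance; vertical axis, 16.3%; both in log2 units), with colour for the group and shape for the replicate number. Both arrays numbered 3 lie to the right, and the saline arrays lie above the LPS arrays.

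Interferon-stimulated genes gave the clearest response to LPS. Ifi44, an interferon-induced protein, rose 6.28-fold, from a log2 value of 4.90 ± 0.32 to 7.55 ± 0.24 (SD, n = 3 each), and was the 1 transcript cluster past the threshold over all clusters (log2 difference 2.65 ± 0.21 SE, limma adjusted p = 0.0395). The median difference over all 36 list members was 0.93, and 35 had a positive difference. All LPS arrays lay above all saline arrays in 27, where chance gives 5% in this direction and 3.61% of all clusters did. When adjusted over the list alone, 25 rose. Among these were Irf7, a transcription factor that drives interferon genes (2.86 ± 0.33), Ifitm3, which restricts virus entry (2.62 ± 0.47), Gbp2, an interferon-induced GTPase (2.28 ± 0.33), Oasl2 (2.06 ± 0.22) and the ubiquitin-like Isg15 (1.51 ± 0.19). The list shifted upward in camera (adjusted p = 2.60e-64), while the call was lost with an estimated correlation (adjusted p = 0.0744 with an estimated correlation). It was the 1 list that moved in one direction by fry (adjusted p = 0.0438). With the replicate block 3 clusters passed instead of 1, namely Ifi44, Oasl2 and Irf7. Ifi44 no longer passed without saline 1, saline 2, LPS 2 or LPS 3, each of which left 0 clusters, and 12 clusters passed without LPS 1.

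**Figure D2:**
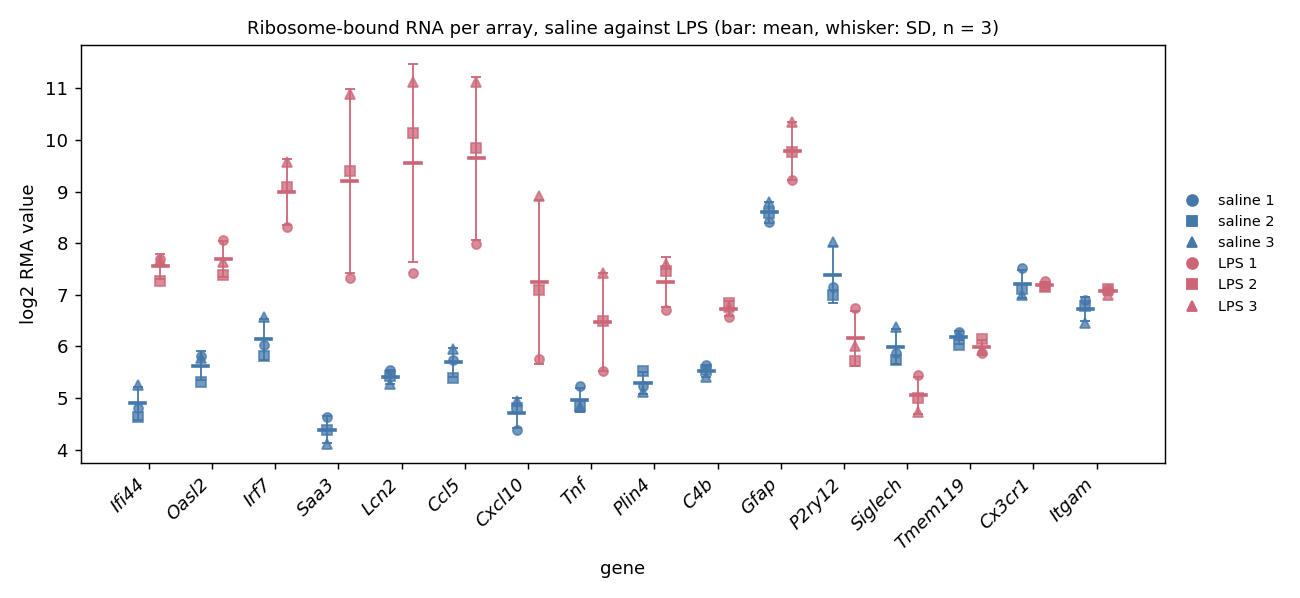
Log2 RMA values (vertical axis) of 16 genes (horizontal axis) in each array, with colour for the group, shape for the replicate number, a bar for the mean and whiskers for the SD of 3 arrays. Ifi44 lay at 7.28 to 7.70 after LPS and 4.63 to 5.25 after saline, whereas Lcn2 after LPS ranged from 7.41 to 11.12.

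Chemokines, which attract leukocytes, shifted upward as a list, with a median of 0.59 and 23 of 24 members positive (camera adjusted p = 9.12e-16; adjusted p = 0.304 with an estimated correlation). No member passed over all clusters, and 4 rose when adjusted over the list alone. These were Ccl5 (3.96 ± 0.66 SE), Ccl3 (3.17 ± 0.77), Cxcl10 (2.55 ± 0.66) and Ccl12 (1.90 ± 0.28), all with 3 LPS arrays above the 3 saline arrays. Ccl2 differed by 1.55 ± 0.56, or 0.83 without LPS 3, and did not pass. The LPS arrays were far apart here: the mean over the list lay 0.29 above the saline mean in LPS 1, 0.77 in LPS 2 and 1.57 in LPS 3, and the list's median was 0.27 without LPS 3 and 0.31 without both arrays numbered 3. The arrays numbered 3 had chemokine values a median of 0.61 higher than the other arrays of their groups, against 0.19 for all genes. This value averages unlike arrays. The list mean lay at -0.02, -0.13 and 0.15 from the saline mean in saline 1, saline 2 and saline 3, so the offset was larger in LPS 3.

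Lists of inflammatory signalling shifted upward by less, and no member passed over all clusters. In each of them the list mean in LPS 1 lay below that in saline 3. As differences from the saline mean these were -0.05 against 0.27 for TLR4 and NF-kB signalling and 0.03 against 0.18 for cytokines. They were 0.04 against 0.10 for feedback inhibitors, 0.04 against 0.21 for the inflammasome list and 0.06 against 0.13 for the oxidative burst list. Proinflammatory cytokines had a median of 0.15 (camera adjusted p = 0.00180; adjusted p = 0.403 with an estimated correlation), with Tnf at 1.51 ± 0.42, Il1a at 1.45 ± 0.57, Il1b at 1.19 ± 0.52 and Il6 at 0.14 ± 0.17, none past the threshold. TLR4 and NF-kB signalling had a median of 0.14 (adjusted p = 0.000112; adjusted p = 0.532 with an estimated correlation), Tlr4 itself differed by 0.01 ± 0.15 (-0.07 to 0.05 with 1 array left out), and the call was lost without LPS 3 (adjusted p = 0.0718, median -0.01). Its median was 0.09 without saline 1 or saline 2, 0.36 without saline 3, 0.29 without LPS 1, 0.22 without LPS 2 and 0.23 with array weights. Feedback inhibitors had a median of 0.20 (adjusted p = 1.54e-07; adjusted p = 0.305 with an estimated correlation), with Zfp36 at 1.36 ± 0.67 and Bcl3 at 1.07 ± 0.34. In the inflammasome and cell death list, with a median of 0.23 (adjusted p = 7.23e-07; adjusted p = 0.373 with an estimated correlation), Mlkl, the effector of necroptosis, rose when adjusted over the list alone (0.89 ± 0.19). The list of oxidative burst, nitric oxide and prostanoids had a median of 0.13 (adjusted p = 8.20e-06; adjusted p = 0.273 with an estimated correlation), with the NADPH oxidase subunit gene Cybb at 0.995 ± 0.36. Without LPS 3 the medians of the cytokines and the feedback inhibitors were 0.04 and 0.07, and that of the inflammasome list was 0.13, as it was over its brighter members. Without LPS 1 the medians of the feedback inhibitors and the inflammasome list were both 0.35 and that of the oxidative burst list 0.20. Without saline 3 those of the cytokines and the oxidative burst list were 0.25 and 0.21. Without LPS 3 the differences of Il1a, Il1b, Zfp36 and Cybb were 0.92, 0.60, 0.69 and 0.57, that of Zfp36 was 2.17 without LPS 1, and that of Il6 was 0.02 without saline 2 and 0.27 without saline 3. The median of the feedback inhibitors was 0.31 without LPS 2 and 0.11 without both arrays numbered 3.

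The 2 greatest differences among genes at an unadjusted p under 0.05 were in acute-phase genes. Saa3, a serum amyloid A protein, differed by 4.83 ± 0.74 (SE), from 4.38 ± 0.26 to 9.21 ± 1.79 (SD, n = 3 each), and Lcn2, which binds bacterial iron carriers, by 4.15 ± 0.79. Both rose when adjusted over the list alone, as did the copper-carrying ferroxidase Cp (1.64 ± 0.37) and the metallothionein Mt2 (1.28 ± 0.36), but none of the 21 members passed over all clusters (limma adjusted p = 0.300 for Saa3 and 0.567 for Lcn2). The acute-phase and iron handling list had a median of 0.35 (camera adjusted p = 8.46e-08; adjusted p = 0.304 with an estimated correlation), which was 0.15 without LPS 3 and 0.17 without both arrays numbered 3. Its mean lay 0.25 above the saline mean in LPS 1, 0.69 in LPS 2 and 1.22 in LPS 3. In saline 1, saline 2 and saline 3 it lay at -0.02, -0.13 and 0.15. The arrays numbered 3 were a median of 0.57 higher than the others, by more in LPS 3 than in saline 3.

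Genes that glucocorticoids are known to induce shifted upward with a median of 0.69 (camera adjusted p = 8.34e-22; adjusted p = 0.206 with an estimated correlation). Of 15 members, 9 rose when adjusted over the list alone and 0 over all clusters. They included Plin4, a lipid droplet protein (1.96 ± 0.25 SE), the cell cycle inhibitor Cdkn1a (1.72 ± 0.39), the kinase Sgk1 (0.97 ± 0.20) and Nfkbia, the inhibitor of NF-kB (0.91 ± 0.22). Cdkn1a and Nfkbia also respond to other signals, DNA damage and NF-kB itself. Mt2 and Zbtb16, also among the 9, had overlapping groups. The list's median was 0.52 without LPS 3 and 0.95 without LPS 1.

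Complement and antigen presentation genes were higher after LPS as lists. Complement had a median of 0.40 over 20 members (camera adjusted p = 2.67e-10; adjusted p = 0.206 with an estimated correlation), and C4b (1.20 ± 0.16) and C1qb (0.67 ± 0.17) rose when adjusted over the list alone. It was also 1 of 2 lists that fry called as changed in either direction (adjusted p = 0.0435), beside the interferon-stimulated genes. The MHC class I list had a median of 0.31 (adjusted p = 1.69e-08; adjusted p = 0.206 with an estimated correlation), with the peptide transporter Tap1 at 0.83 ± 0.22 and the immunoproteasome subunit Psmb8 at 0.79 ± 0.21, neither past the threshold. The MHC class II and costimulation list had a median of 0.19 (camera adjusted p = 0.00226, or 0.373 with an estimated correlation). Its mean in LPS 1 lay below that in saline 3 (0.05 against 0.13 from the saline mean). Without LPS 3 the medians were 0.27 for complement, 0.18 for MHC class I and 0.10 for MHC class II. Without both arrays numbered 3 those of complement and MHC class I were 0.24 and 0.21. That of MHC class II was 0.11 over its brighter members.

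Resting microglia markers shifted downward, with a median of -0.27 and 20 of 24 members negative (camera adjusted p = 1.59e-06; adjusted p = 0.206 with an estimated correlation), and no member passed even within the list alone. P2ry12, a receptor for ADP by which microglia sense injury, stood at 7.39 ± 0.55 after saline and 6.15 ± 0.54 after LPS (SD, n = 3 each), a difference of -1.24 ± 0.34 SE, and Siglech differed by -0.94 ± 0.24, each with the LPS arrays below all saline arrays. Other markers of the same cells were nearer to 0: Csf1r differed by -0.25 ± 0.24, Tmem119 by -0.20 ± 0.16 and Cx3cr1 by -0.02 ± 0.18. Itgam, the gene of CD11b whose promoter drives the tag, differed by 0.35 ± 0.17, Rpl10a, whose protein carries the tag, by 0.20 ± 0.31, Aif1 by -0.22 ± 0.24 and Ptprc, the leukocyte antigen CD45, by 0.48 ± 0.19, none past the threshold. Leaving out single arrays moved Csf1r between -0.45 and -0.07, Cx3cr1 between -0.12 and 0.14, Aif1 between -0.37 and -0.001, Itgam down to 0.22, and Rpl10a between -0.03 and 0.49. The list's median was -0.17 without LPS 3 and -0.18 without saline 1.

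The list of disease-associated microglia genes had a median of 0.07 (camera adjusted p = 0.0124; adjusted p = 0.594 with an estimated correlation), and its call was lost without saline 2 (adjusted p = 0.307, median -0.04) and without LPS 3 (adjusted p = 0.164, median -0.04). That median was 0.20 without saline 3, 0.23 without LPS 1, 0.03 with arrays centred on their medians and 0.11 over brighter members. Its direction thus depends on single arrays. The lysosome and phagocytosis list had a median of 0.10 (adjusted p = 0.000281; adjusted p = 0.304 with an estimated correlation), in which the protease gene Ctsc rose when adjusted over the list alone (0.89 ± 0.17), and the call was lost without saline 3 (adjusted p = 0.204, median 0.01). Its median was 0.23 without saline 1, 0.15 without LPS 1 and 0.07 with arrays centred on their medians. Alternative activation genes, with a median of 0.03, were not shifted (adjusted p = 0.343). Their median ran from -0.02 without LPS 3 to 0.09 without saline 3, and was -0.001 with repeated quantile normalization and -0.005 with arrays centred on their medians. They passed over their brighter members (adjusted p = 0.00759, median 0.12).

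Genes of cholesterol synthesis and sterol export shifted downward, with a median of -0.25 and 17 of 20 members negative (camera adjusted p = 9.84e-05; adjusted p = 0.206 with an estimated correlation). Cyp51, a demethylase of the pathway, differed by -0.57 ± 0.20 SE and Idi1, an isomerase of it, by -0.51 ± 0.21, neither past the threshold. The median was -0.16 without LPS 2. Immediate early genes, which neurons and other cells induce on stimulation, had a median of -0.06 (adjusted p = 0.0124; adjusted p = 0.437 with an estimated correlation). Within that list alone Egr3 fell by 0.64 on the log2 scale (-0.64 ± 0.16) and Klf2 rose by 0.66 (0.66 ± 0.16). The call was lost without saline 1 (adjusted p = 0.229), LPS 2 (0.0586, median 0.02) and LPS 3 (0.0895, median -0.17). It was also lost with repeated quantile normalization (0.0805) and with arrays centred on their medians (0.0743, median -0.09) or on the mean of ribosomal protein genes (0.0556). The median was also -0.14 without saline 2, -0.03 without saline 3, -0.11 without LPS 1, -0.14 with array weights and -0.10 without both arrays numbered 3.

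Markers of other cell types were measured beside these genes. Neutrophil markers shifted upward, with a median of 0.21 (camera adjusted p = 5.78e-05; adjusted p = 0.304 with an estimated correlation), which was 0.04 without LPS 3 and 0.13 over brighter members. The list mean in LPS 1 lay 0.03 above the saline mean, below that in saline 2 (0.06) and saline 3 (0.04). S100a9 rose when adjusted over the list alone (1.22 ± 0.24 SE), and S100a8 differed by 1.47 ± 0.44, with LPS 1 (4.56) below saline 2 (4.75). Both encode calcium-binding proteins that are abundant in neutrophils and are also induced in other myeloid cells. Astrocyte markers had a median of 0.09 (camera adjusted p = 0.0400, or 0.437 with an estimated correlation). Gfap, the intermediate filament of astrocytes, stood at 8.60 ± 0.20 after saline and 9.78 ± 0.56 after LPS (SD, n = 3 each). It passed narrowly when adjusted over the astrocyte list alone (limma adjusted p = 0.0489) and did not pass over all clusters. That list's call was lost without saline 2 (adjusted p = 0.137), saline 3 (0.877, median 0.03), LPS 1 (0.230, median 0.05) and LPS 2 (0.179). It was also lost with arrays centred on their medians (0.0635, median 0.05) or on the mean of ribosomal protein genes (0.0556), with array weights (0.499, median 0.04) and without both arrays numbered 3 (0.291). Oligodendrocyte lineage markers had a median of -0.12 (adjusted p = 0.0270; adjusted p = 0.532 with an estimated correlation). The call was lost without saline 1 (0.0602), saline 3 (0.0905, median -0.02), LPS 1 (0.0506) and LPS 2 (0.179, median -0.03) and with repeated quantile normalization (0.102, median -0.08). The median was -0.22 without LPS 3 and -0.18 with array weights. Endothelial activation genes had a median of 0.12 (adjusted p = 0.00344; adjusted p = 0.478 with an estimated correlation). The call was lost without saline 3 (adjusted p = 0.328), with array weights (0.157, median 0.04), over brighter members (0.139, median 0.08) and without both arrays numbered 3 (0.339, median 0.03). The median was 0.06 without LPS 3 and 0.20 without LPS 1.

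The remaining cell type lists were not shifted. Blood monocyte markers had a median of 0.15 (camera adjusted p = 0.108) and passed without LPS 1 (adjusted p = 0.0176), over members of no other list (0.0340) and with arrays centred on the mean of ribosomal protein genes (0.0424). The median was 0.06 without LPS 3 and 0.08 without both arrays numbered 3. Neuron markers had a median of -0.04 (adjusted p = 0.346). They passed downward without saline 3 (0.000231, median -0.13) or LPS 1 (0.0113, median -0.11) and with array weights (0.0492). The median was 0.02 without saline 2 and 0.05 without LPS 3. The adjusted p was 0.306 for border macrophage markers, 0.990 for lymphocyte and NK cell markers, 0.481 for endothelial and mural cell markers and 0.744 for erythroid markers.

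Lists of general cell functions were not shifted either. Cytosolic ribosomal proteins had a median of 0.03 (camera adjusted p = 0.658), translation initiation and elongation factors 0.005 (adjusted p = 0.868) and SR splicing factors -0.04 (adjusted p = 0.398), among which Srsf3 differed by 0.01 ± 0.21 SE. With 1 array left out the medians ran from -0.05 to 0.04 for the translation factors, from -0.12 to 0.04 for the SR factors and from -0.06 to 0.06 for cell cycle genes. Srsf3 ran from -0.12 to 0.21 and Actb, below, from -0.15 to 0.15. The reference genes Actb and Hprt differed by 0.03 ± 0.19 and -0.10 ± 0.14. The adjusted p was 0.881 for cell cycle genes, whose median of 0.02 and mean of -0.01 differ in sign, 0.114 for glycolysis and 0.658 for endoplasmic reticulum stress. Oxidative phosphorylation, with a median of -0.07, missed the threshold (adjusted p = 0.0721). It passed with the replicate block (adjusted p = 0.0406), without saline 2 (0.0252), without LPS 1 (0.0379), with arrays centred on their medians (0.0416) or on the mean of ribosomal protein genes (0.0424) and with a term for the arrays numbered 3 (0.0392). Its median was 0.02 without saline 3, -0.13 without saline 2 and -0.14 without LPS 3. Ribosomal proteins passed without saline 3 (0.0306, median 0.20) or LPS 1 (0.0286, median 0.19), but the median was -0.12 without saline 2, -0.03 without saline 1 and -0.13 without LPS 3. The sign of that median thus depends on single arrays. Glycolysis passed without saline 1 (0.0149), saline 2 (0.00677, median 0.12) or LPS 3 (0.00358) and over descriptions naming 1 gene (0.0406). Y-linked and X-inactivation transcripts had a median of 0.10 (adjusted p = 0.658) and passed without saline 2 (0.0388, median 0.40). Their median was 0.38 without LPS 2, -0.11 without saline 1 and -0.12 without LPS 1. They varied between arrays of a group, with Ddx3y at 9.001 in saline 2 and 9.02 in LPS 1 and at 7.36 to 7.86 in the other 4. Ddx3y differed by 0.20 ± 0.48 and Xist by 0.57 ± 0.49 between the groups, and with single arrays left out by -0.22 to 0.71 and by 0.12 to 1.20.

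**Figure D3:**
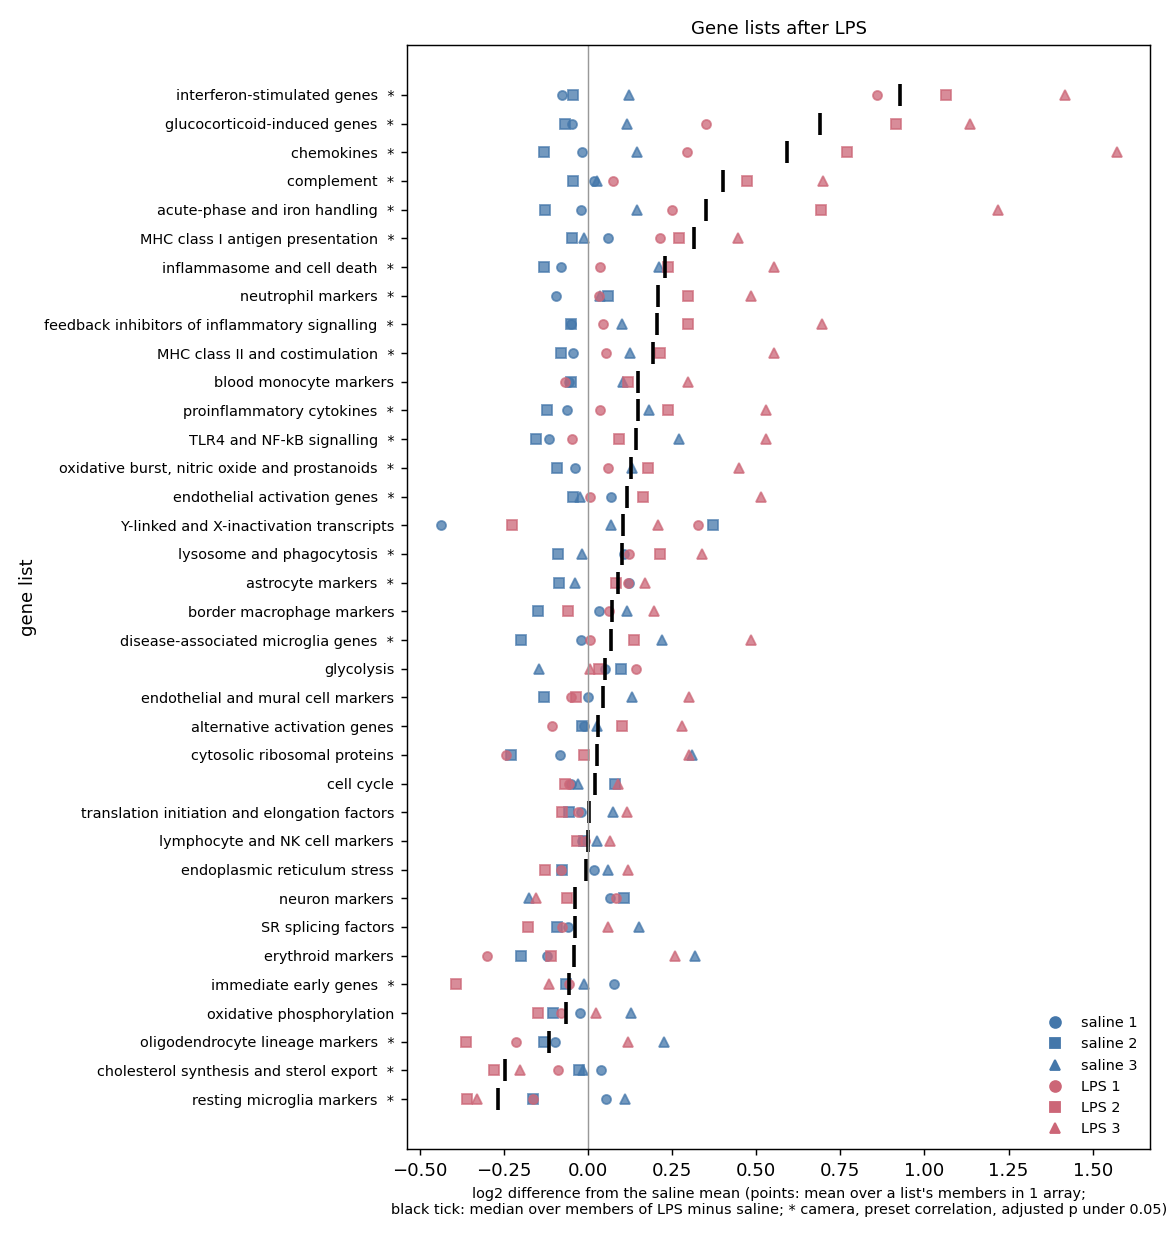
Log2 difference from the saline mean (horizontal axis) for the 36 gene lists (vertical axis): each point is the mean over a list's members in 1 array, with colour for the group and shape for the replicate number, the black tick is the median over members of LPS minus saline, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes have the median farthest from 0 (0.93) and resting microglia markers the lowest (-0.27).

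Over all 34472 clusters, limma called 1 higher and 0 lower after LPS at an adjusted p under 0.05, and the second smallest adjusted p was 0.142 (Oasl2, Rtp4, Gbp7 and Irf7). At an unadjusted p under 0.05 there were 512 higher and 266 lower clusters, 2.26% of those tested, of which 83 were at least 2-fold higher and 4 at least 2-fold lower. These counts depend on single arrays: without LPS 3 there were 408 higher and 610 lower, and without saline 3 there were 1022 and 332. With the replicate block they were 1145 and 870. Centring each array on its median changed the 512 and 266 to 524 and 559, and centring on the mean of ribosomal protein genes to 392 and 194. Another scaling, fixed beforehand, centred each array on the median level of the ribosomal protein genes and gave 2033 and 34. That level differed by -0.18, while the median of the genes' own differences was 0.03. This scaling therefore raised every difference by 0.18, the ribosomal protein list itself to 0.21, and did not hold those genes equal. Under it alone among the scalings the medians of the oligodendrocyte (0.07), immediate early (0.13), neuron (0.14) and oxidative phosphorylation (0.12) lists were positive, and those of resting microglia and cholesterol genes were -0.08 and -0.06. The astrocyte call was also lost under it (adjusted p = 0.121). Groups did not overlap in 6.71% of clusters, where chance gives 10% if the arrays are exchangeable. The offset shared by both arrays numbered 3 spreads each group and makes overlap likelier. The 6.71% therefore does not show less separation than chance. In the authors' deposited table, a p under 0.05 was listed for 1080 clusters, of which 55 were at least 2-fold higher and 2 at least 2-fold lower, and the smallest adjusted p was 0.999886. By camera with the preset correlation 21 of the 36 lists were shifted, 17 upward and 4 downward, and 0 were with an estimated correlation.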

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

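The settings with all clusters of the value table, a term for the arrays numbered 3, without both arrays numbered 3, the Y-linked level as a covariate, the replicate block with an intensity trend and robust prior or with an estimated correlation, descriptions naming 1 gene, and centring on the mean of ribosomal protein genes were chosen after seeing the data; the others were fixed before. With group as the only term limma called 1 cluster (0 lower, 1 at least 2-fold, 1 named gene). The counts of clusters changed, higher, at least 2-fold and of named genes all went to 3 with the replicate block, 22 with array weights, 2 with the term for the arrays numbered 3, without both of them and with centring on the mean of ribosomal protein genes, and 0 with the unmoderated test (where 1080 had an unadjusted p under 0.05), with all clusters (1083) and with the Y-linked covariate (650). Centring on the median level of ribosomal protein genes gave 41 clusters, 41 higher, 41 at least 2-fold and 39 named genes, but it raised all differences by 0.18 and did not hold those genes equal (their list stood at 0.21), and the block with an intensity trend and robust prior gave 32, 32, 29 and 28. Leaving out 1 array gave 0 to 12, with 12 without LPS 1. No setting run called a lower cluster. Clusters at an unadjusted p under 0.05 and at least 2-fold numbered 87, and 148 with that centring, 48 with the unmoderated test, 178 with all clusters, and 94 to 184 with 1 array left out. Ifi44 passed in 16 of its 23 alternatives, with adjusted p from 0.000372 to 0.99988 and log2 differences from 2.52 to 2.83. The cause of these moves was not tested. Gene lists shifted numbered 21, and from 18 to 23 with 1 array left out. With an estimated correlation they numbered 0, with the block or without it. The estimate, which ran up to 0.590, widens the test by construction. With it camera also refers its statistic to the few residual degrees of freedom of the arrays instead of to the number of genes. The fall to 0 thus has 2 sources, which were not told apart. Cholesterol genes, with an estimate of 0.056, went from a camera p of 3.28e-05 to 0.0343. Among the camera and cluster calls, the block changed no other than those given with the oxidative phosphorylation list and the cluster counts. Fry and the adjustment over a list alone were not run with the block. Over single lists 701 of the alternative tests kept camera's direction and side of the threshold, 70 lost the call, 20 gained one and 36 changed direction without a call; over single named genes these numbers were 1889, 7, 23 and 29. None of them was called in the opposite direction. The other deposited table was not run because it holds no values per array. RMA compresses changes in dim clusters. Il6 was dim (3.09 after saline) and showed no clear difference, and whether a change of it was hidden was not tested. Among the brighter clusters 1 was called.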

Other observations

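Genes outside the lists also stood higher after LPS, chosen here by small p after their values were seen, and none passed over all clusters. Serpina3n, a protease inhibitor of the acute-phase response, differed by 2.29 ± 0.31 (SE; limma adjusted p = 0.164), Ms4a6d, a membrane protein of myeloid cells, by 2.02 ± 0.25 (0.148), the fatty acid receptor Gpr84 by 1.87 ± 0.33 (0.549), Rtp4, an interferon-induced chaperone, by 1.49 ± 0.16 (0.142), the GTPase Gbp7 by 1.49 ± 0.17 (0.142), Lgals3bp by 1.37 ± 0.26 (0.567), the protease inhibitor A2m by 1.33 ± 0.25 (0.567), Apod, a lipid carrier, by 1.24 ± 0.23 (0.567) and the membrane-cytoskeleton linker Msn by 1.01 ± 0.16 (0.317). All of these had the 3 LPS arrays above the 3 saline arrays.

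The LPS arrays differed in how far some lists moved, as values only. Mean differences from the saline mean in LPS 1, LPS 2 and LPS 3 were 0.86, 1.06 and 1.42 for interferon-stimulated genes, 0.35, 0.92 and 1.14 for glucocorticoid-induced genes, and 0.07, 0.47 and 0.70 for complement. Resting microglia markers lay at -0.16, -0.36 and -0.33, against 0.05, -0.16 and 0.11 in saline 1, saline 2 and saline 3. Saline 2 was thus as low as LPS 1. Lcn2 stood at 7.41, 10.14 and 11.12, and Ifi44 at 7.70, 7.28 and 7.67.

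Of the tests that follow, those of the male and female makeup, the Xist correlation included, of neuronal RNA and of astrocyte RNA were chosen only after the result was seen. Both arrays numbered 3, one per group, stood apart. Repeating quantile normalization left 78.7% of the variance of the first component and both arrays still outside the range of the others, which argues against overall brightness as the whole cause. Their mean Y-linked level of 6.41 lay inside the 5.70 to 7.17 of the other arrays, against a male and female makeup as the cause. Neuron markers had the lowest median of all lists in these arrays (-0.28, against 0.19 for all genes), as a lower share of neuronal RNA would give, but such a share would also raise oligodendrocyte and astrocyte markers alike, and their medians differed by 0.37 (0.30 against -0.07, two-sided permutation p = 0.0341 with 100000 resamples over genes, which are not independent replicates), which argues against it as the whole cause. A part played by it, a shared day or batch of preparation, and a biological cause, stay open, and the last 2 were not tested, since the labels give no batch.

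Gfap was higher in all 3 LPS arrays, by 1.19. A larger share of astrocyte RNA in the LPS purifications would bring the other astrocyte markers along, but their median was 0.0827 with an SD of 0.20 over members, which argues against it. The astrocyte markers Glul and Aldoc stood at 11.95 and 11.61 after saline and 12.02 and 11.75 after LPS. No array measured unpurified RNA, so these signals cannot tell how much astrocyte RNA was co-purified. Whether the labels' treatment changed Gfap within astrocytes whose RNA was co-purified, or in the tagged cells, remains a hypothesis that no value here tests.

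Y-linked transcripts differed between pools of one group, with mean levels of 5.70, 7.11 and 6.42 in saline and 7.17, 5.85 and 6.39 in LPS. The labels give each group of 5 mice an equal ratio of the sexes, which 5 mice cannot hold exactly. Whether that alone would give a range as wide as 5.70 to 7.17 was not tested. Repeated quantile normalization left 100.1% of their range, against overall brightness. An uneven male and female makeup of the pools is a candidate explanation and would make Xist take the opposite course. The mean of Ddx3y, Eif2s3y, Kdm5d and Uty against Xist gave Pearson r = -0.55 (exact permutation p = 0.256, adjusted 0.256; -0.72 without the 2 arrays farthest from the median) and Spearman rho = -0.60 (exact permutation p = 0.242, adjusted 0.256) over 6 arrays, so that course was not shown and the explanation stays open.

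The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For clusters changed the real split gave 1 and the highest other 9, and 2 of the 10 splits gave as many. For clusters at an unadjusted p under 0.05 and at least 2-fold the values were 87 and 381, and 3 splits gave as many. For lists shifted both were 21, and 2 splits gave as many. The splits with 9 and 381 clusters both put the arrays numbered 3 in the same group and point to that structure of the arrays. Among the 4 splits that part all pairs of equal number, the 3 others gave 0 clusters changed, 13 to 20 at an unadjusted p under 0.05 and at least 2-fold, and 1 to 21 lists, where the one with 21 lists exchanged the arrays numbered 1.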
